A study of Mus musculus with 6 samples.

How the data were processed

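The series holds 6 samples of mouse tissue, 1 for each diet of the dam (control, CT, or high-fat with maternal obesity, MO) in placenta with yolk sac at E13.5, liver at E13.5 and liver at E17.5. Per the labels' protocols, tissue of 9 embryos per group was pooled, minced and digested with collagenase, red cells were not lysed, and libraries were made with the 10x GEM-X Single Cell 3′ v4 kit and sequenced on a NextSeq 2000. Per the labels, the series text also speaks of replicates from several litters, but each group has 1 sample, so each was treated as 1 library with no replicate. Placenta and yolk sac were collected together, so blood of the mother can be among the cells.

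The values used are the deposited UMI counts per gene and barcode, whole numbers that were not normalized, which the authors made with Cell Ranger 8.0.1 against mm10, per the submitters' processing notes and the file headers. How barcodes were chosen before deposit is not given in the sources used here. The E13.5 liver matrices hold exactly 10000 barcodes each and end at 3305 (CT) and 2125 (MO) UMIs, while the other matrices end at 500. The E17.5 liver samples have 2 matrices each, so there are 8 matrices. The matrices of 1 sample share 15172 (CT) and 12150 (MO) barcodes, against 20 to 49 for the other 15 pairs of libraries, so they were treated as repeat processing of 1 capture, and the matrix with more UMIs was used. The matrices list 32285 genes, with 40 repeated symbols. Coordinates of globin genes come from the mm10 annotation given for this work, matched by gene ID.

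Barcodes with at least 500 UMIs, at least 100 genes and under 15% mitochondrial UMIs were kept. Scrublet (in scanpy 1.11.5, expected rate 6%) was set to count only where it called 0.5% to 20% of barcodes. It called under 0.5% in 5 of 6 libraries, so it did not work there and doublets remain in these. In the E17.5 MO liver it called 0.563%, which left 12015 of 12083 barcodes. Counts were scaled to 2000 per barcode and log-transformed, and 2000 variable genes without globin, heme, iron, mitochondrial, Xist and Y genes gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1.0, over both diets of a tissue and day. Clusters were named from fixed markers, at least 3 of them detected. The first naming rule, on fold against all other cells, was replaced after clusters were seen, and the exclusion of clusters led by ribosomal RNA repeat or muscle genes was added then too. Tools were Python 3.11.15, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors alone.

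UMIs were summed per library and class of at least 100 cells in each library. Hepatocyte-like cells of E17.5 liver (71 CT and 73 MO cells) fell below that and have no gene comparison. Gene levels are UMIs scaled to the same total of non-globin UMIs (CPM), and ratios are log2 with 0.5 added to each sum. Intervals are exact at 95%, Clopper-Pearson for shares and conditional binomial for ratios, and cover counting error only. They are narrow because the sums are deep, and they say nothing of the spread between animals. A share of 0 is given with its upper limit. A cell's beta-like globin was called mostly embryonic where Hbb-y plus Hbb-bh1 exceeded 0.5 of at least 20 beta-like UMIs, and cells from 0.3 to 0.7 were counted as near that share.

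Genes were named by a fixed rule. They had at least 200 UMIs over both libraries and were not clone, predicted, mitochondrial, ribosomal protein, globin, Xist or Y genes. They also reached at least 20% of the level of every other named class with at least 100 cells over both libraries. Between days, named classes of any size counted. A gene below that 20% may come from RNA of other cells and was set aside. Smaller classes and unnamed cells were not compared. They were ranked by the interval bound nearest to 0, and the 10 highest and 10 lowest were taken, or 5 each for the days. The rule considered 3475 genes in placenta erythroid-like, 2342 in giant cell-like, 7911 in E13.5 erythroid-like, 4849 in hepatocyte-like and 7848 in E17.5 erythroid-like cells. Of these, 1247, 179, 691, 172 and 1521 were set aside and not ranked. Of each list, the 2 highest and 2 lowest members with 200 UMIs could be named too. List medians use members with at least 20 UMIs, and their percentile is among 10000 random lists of the same size matched on expression in 20 bins.

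The ratios were tested on simulated counts with 200 genes changed in each erythroid-like comparison, 50 for each of log2 −1, −0.5, 0.5 and 1. All had the right sign (100%). Intervals held the true value for 92% to 96% of changed genes in placenta with yolk sac (3672 genes), 92% to 98% in E13.5 liver (8277) and 88% to 100% in E17.5 liver (8265), the lowest at log2 1, and for 95.7%, 95.5% and 95.3% of unchanged genes. Random unchanged lists of 15 genes fell outside the middle 95% in 3.5%, 4% and 6.5% of 200 draws.

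Alternatives were no barcode filter, at least 1000 UMIs and 300 genes, no doublet removal, Leiden resolution 2.0, the other E17.5 matrices, other limits for embryonic cells, scaling to all UMIs with globins or by edgeR's TMM factors, and list minimums of 100 UMIs or none. Lists, markers, the rule for named genes and these alternatives were fixed before the data were examined. After that, alternatives were added for doublet scores, the lower UMI edge, the clusters led by ribosomal RNA repeat genes, the interferon-led cluster, cluster 12 of placenta with yolk sac and a common cluster composition, in which each cluster with at least 20 cells in each library gets the same weight in both.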

Results

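The series asked how obesity of the mother before and during pregnancy bears on red cell formation in the fetus. Female C57BL/6 mice ate either a control diet (10% of energy from fat, the CT group) or a high-fat diet (45%, the maternal obesity or MO group) and were mated once their weights differed by more than 20%. Single cells from placenta with yolk sac (E13.5) and from fetal liver (E13.5 and E17.5, days of embryonic life) were profiled by droplet-based 3′ RNA sequencing, without lysis of red cells. There was 1 library per diet, tissue and day, and each pooled tissue from 9 embryos. No difference between diets therefore has a replicate check. No significance test was run between diets, and the intervals in brackets are exact 95% intervals that cover counting error only. The libraries held 69387370 (CT) and 73762299 (MO) unique molecular identifiers (UMIs) in 10380 and 11372 barcodes of placenta with yolk sac, 45835231 and 30305007 in 10000 and 10000 barcodes of E13.5 liver, and 69196208 and 69286862 in 15467 and 12255 barcodes of E17.5 liver. The filters kept 7136 and 8047, 10000 and 10000, and 15262 and 12083 barcodes, with a median of 4517.5 and 5566, 4263 and 2741, and 3808.5 and 4707 UMIs.

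Erythroid-like cells were the most numerous named class in every library. They made up 42.5% (41.4 to 43.7) of CT and 49.4% (48.3 to 50.5) of MO cells in placenta with yolk sac, 75.9% (75.0 to 76.7) and 67.8% (66.9 to 68.7) in E13.5 liver, and 65.9% (65.1 to 66.7) and 67.7% (66.8 to 68.5) in E17.5 liver. All class names rest on markers and mean "like" the named type. Clusters led by ribosomal RNA repeat genes stayed unnamed and held 1349 CT and 1336 MO cells of placenta with yolk sac and 1645 and 901 of E17.5 liver, and a muscle-led cluster of E13.5 liver held 26 and 16.

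**Figure D1:**
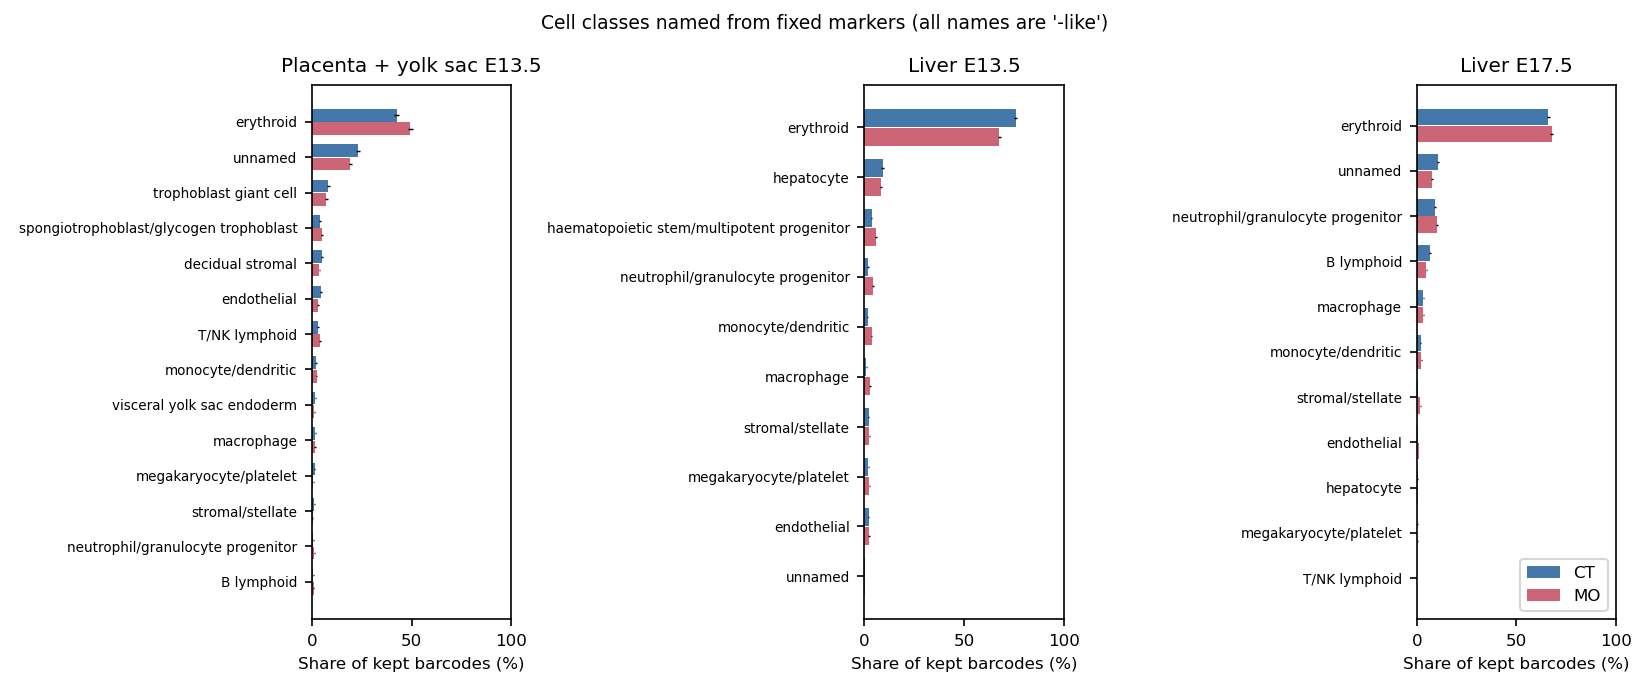
Bars give the share of kept barcodes (%) in each marker-named class for CT (blue) and MO (red) libraries of placenta with yolk sac, E13.5 liver and E17.5 liver, and the thin lines are exact 95% intervals of counting error. Erythroid-like cells form the longest bars, from 42.5% in CT placenta with yolk sac to 75.9% in CT E13.5 liver.

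The globin genes read here lie in 2 clusters of the mm10 genome. The beta-like genes are on chromosome 7, where Hbb-bt spans 103812524 to 103813996, Hbb-bs 103826534 to 103828096, Hbb-bh2 103839124 to 103840520, Hbb-bh1 103841637 to 103843164 and Hbb-y 103851749 to 103853216. The alpha-like genes are on chromosome 11, where Hba-x spans 32276400 to 32278116, Hba-a1 32283511 to 32284465 and Hba-a2 32296489 to 32297298. Hbb-y, Hbb-bh1 and Hba-x are the embryonic forms made by primitive red cells of the yolk sac, and Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 the adult forms. Adult copies are close to identical in sequence, so counts of Hbb-bs against Hbb-bt and of Hba-a1 against Hba-a2 are uncertain.

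The first comparison was MO against CT in E13.5 liver, the main site of definitive red cell formation at that age. Erythroid-like cells of the MO liver carried more globin RNA, at 27.4% of their UMIs (27.3 to 27.4) against 14.6% (14.6 to 14.6) in CT. In these cells the difference of 12.7 percentage points fell to 4.56 with a common cluster composition, and it also fell above a common UMI floor. Of the 7911 genes that the naming rule considered there, 691 were set aside. Among the rest, Xpo7 ranked highest, at a log2 ratio of MO over CT of 1.43 (1.367 to 1.497). Among embryonic globins, Hbb-y took 1.89% of globin UMIs in MO and 1.23% in CT, while Hbb-bh1 took 0.0974% in MO and 0.170% in CT. Neutrophil or granulocyte progenitor-like, monocyte-like and macrophage-like cells took larger shares of the MO liver.

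In that tissue the 10 highest genes of erythroid-like cells ran from Slfn14 at 1.47 (1.33 to 1.61) to Ube2h at 1.06 (0.96 to 1.16). They included Tmcc2 at 1.29 (1.23 to 1.35), Bpgm, whose product sets the oxygen affinity of haemoglobin, at 1.29 (1.18 to 1.40), Tent5c at 1.23 (1.13 to 1.33) and the ubiquitin ligase gene Mkrn1 at 1.18 (1.12 to 1.25), with Tcp11l2, Gpcpd1 and Ypel3 between. The 10 lowest ran from Adcy10 at −1.43 (−1.73 to −1.15) to Hspa8, a chaperone gene, at −0.43 (−0.45 to −0.41). Jun, an immediate early gene, stood at −0.58 (−0.64 to −0.52), and Mid1 at −0.72 (−0.87 to −0.58). Cells of this class were most numerous in clusters 0, 2, 3, 7 and 9 in CT and in clusters 7, 9, 4, 3 and 2 in MO, and several of the highest genes also lead clusters 4, 7 and 8. With both libraries given the same cluster composition, Xpo7 stood at 0.54, Slfn14 at 0.54, Bpgm at 0.43 and Adcy10 at −1.24.

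The heme synthesis list had 14 of 15 members higher in MO, with a median log2 ratio of 0.19, at percentile 99.9 among 10000 random lists matched on expression. With a common cluster composition, only 5 of 15 were higher and the median was −0.078. Alas2, the first enzyme of heme synthesis in red cells, stood at 0.91 (0.85 to 0.96) and Fech, which inserts the iron, at 0.55 (0.50 to 0.60). Genes of mitophagy and enucleation were higher in 15 of 19 members, with a median of 0.39, which fell to 0.061 with a common cluster composition, inside the range of random lists. Of erythroid iron handling, 13 of 19 members were higher with a median of 0.10 (10 of 19 and 0.021 with a common cluster composition, inside the range of random lists), among them Ncoa4 at 0.78 (0.67 to 0.89) and the mitochondrial iron importer Slc25a37 at 0.71 (0.67 to 0.74). Mitochondrially encoded transcripts had a median of 0.18, with 9 of 13 higher, and nuclear oxidative phosphorylation genes 0.05, with 35 of 58 higher. When globin UMIs were counted in the scale, the medians of heme synthesis, iron handling, mitochondrially encoded and oxidative phosphorylation genes turned to −0.047, −0.13, −0.049 and −0.19. Globin switching regulators lay near their matched lists at −0.04, with Sox6 at 0.65 (0.60 to 0.70) and Myb at −0.32 (−0.42 to −0.22). S phase genes were at −0.07 and G2 and M phase genes at 0.04, and with a common cluster composition at −0.063 and −0.062, both below the range of random lists. Interferon response genes had a median of 0.56, with 12 of 14 measured members higher and Isg15 at 1.68 (1.42 to 1.94), but only 3 of these members reached 20% of the level of every other class, and their median was 0.11. Markers of other cells moved along with them in these erythroid-like cells, with a median of 1.02 for the fetal hepatoblast list and 1.40 (1.32 to 1.47) for Afp.

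The embryonic share of beta-like globin UMIs was 2.84% (2.82 to 2.86) in MO and 2.00% (1.98 to 2.01) in CT, and that of alpha-like globin UMIs 0.867% (0.853 to 0.882) and 0.817% (0.803 to 0.832). By cluster, the beta-like share was higher in MO in 4 of the 9 erythroid-like clusters, as in cluster 4 (4.65% and 1.52%), and lower in 5, as in cluster 8 (3.27% and 8.11%). Cells whose beta-like globin was mostly embryonic numbered 86 of 6779 in MO (1.27%, 1.02 to 1.56) and 50 of 7571 in CT (0.660%, 0.491 to 0.870), with 171 and 72 cells near the dividing share, and the difference turned to −0.0499 points with a limit of 0.7. In hepatocyte-like cells, which should not make globin, globins took 7.81% of UMIs in MO and 4.99% in CT, and the embryonic beta-like share was 2.55% and 1.83%. Neutrophil or granulocyte progenitor-like cells formed 4.3% (3.91 to 4.72) of MO and 1.84% (1.59 to 2.12) of CT cells, monocyte or dendritic-like cells 3.69% and 1.80%, macrophage-like cells 2.76% and 1.08%, and haematopoietic stem or multipotent progenitor-like cells 5.72% and 3.68%, a class that had no cluster at Leiden resolution 2.0. The deposited barcodes end at 3305 UMIs in CT and 2125 in MO. With only barcodes above the higher of these, the globin difference fell from 12.7 to 4.80 percentage points, the erythroid-like share differed by −22.7 in place of −8.11 points, and the heme synthesis median became −0.13 and the alpha-like difference −0.0264 points. With a common cluster composition, the globin difference was 4.56 points.

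**Figure D2:**
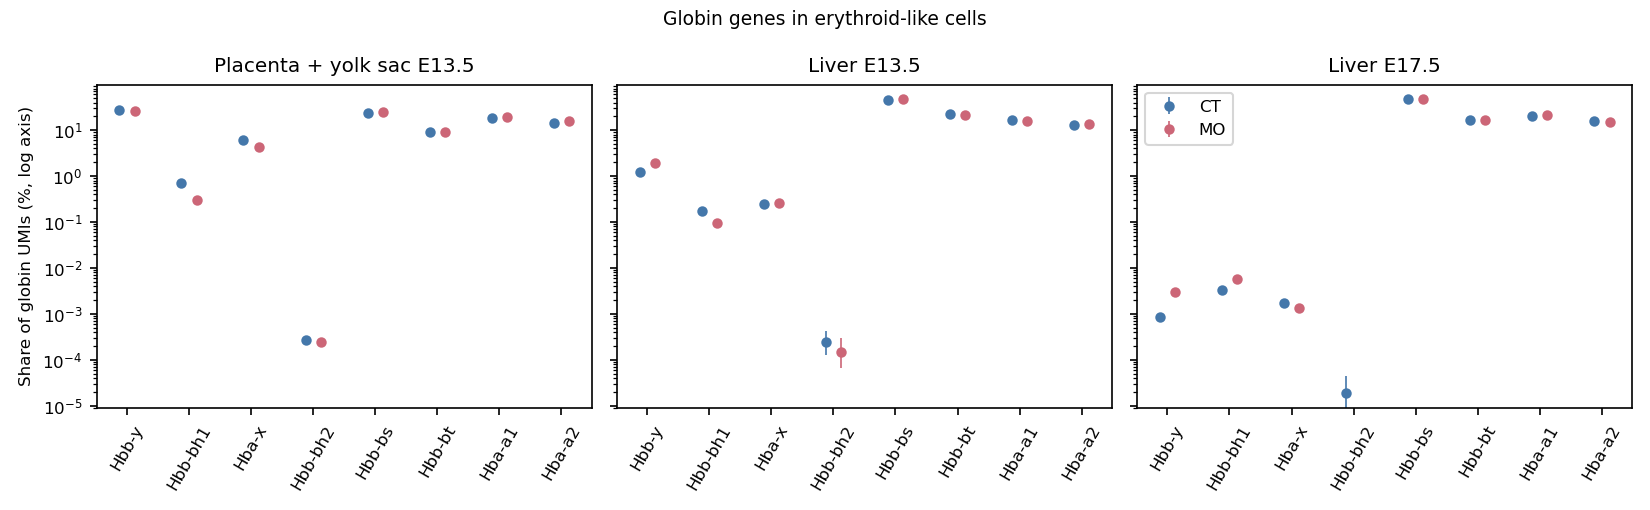
Points give each globin gene's share of all globin UMIs in erythroid-like cells (%, log axis) for CT (blue) and MO (red), with exact 95% intervals of counting error, in the 3 tissues; Hbb-bh2 had no UMI in MO E17.5 liver and has no point there. Embryonic Hbb-y took 27.0% of globin UMIs in CT placenta with yolk sac, 1.23% in CT E13.5 liver and 0.000845% in CT E17.5 liver.

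Hepatocyte-like cells of the E13.5 MO liver had lower transcript levels of lipid synthesis genes, and of hepatocyte maturation genes, than those of the CT liver. All 16 cholesterol synthesis genes were lower (median log2 ratio −0.33, percentile 0 of the matched lists), from Mvd at −0.75 (−1.09 to −0.43) and Dhcr7 at −0.56 (−0.84 to −0.29) to Insig1 at −0.13 (−0.39 to 0.13). All 11 measured fatty acid synthesis genes were lower too, with a median of −0.32, among them the carbohydrate-sensing factor Mlxipl at −0.48 (−0.91 to −0.08) and Elovl6 at −0.38 (−0.57 to −0.19). Apob, the structural protein of lipoproteins, stood at −0.43 (−0.50 to −0.35). Of the unfolded protein and integrated stress response list 15 of 17 members were lower (median −0.17), and of the fetal hepatoblast list 9 of 12 (median −0.22), with Igf2 at −0.34 (−0.40 to −0.28) and Mest at 0.93 (0.58 to 1.29). Ribosomal protein genes (68 of 80, median 0.11) and nuclear oxidative phosphorylation genes (46 of 58, median 0.13) were mostly higher. The genes ranked highest were March3 at 1.56 (1.42 to 1.71), Sox6 at 1.36 (1.17 to 1.56) and Specc1 at 1.30 (1.12 to 1.49), and 9 of the 10 had erythroid-like cells as the class with the highest level elsewhere. Hepatocyte maturation genes were lower in 9 of 10 (median −0.18), with Alb at 9684 CPM in MO and 12194 in CT, while heme synthesis (12 of 15, median 0.14) and angiogenesis genes (8 of 8, 0.92) were higher, so the lipid lists were not alone in shifting. Hepatocyte-like cells numbered 915 in CT and 827 in MO. Globins took 7.81% of their UMIs in MO and 4.99% in CT. More RNA of erythroid cells in the MO barcodes would lower the levels of hepatocyte genes in general. This was not tested, so a change in lipid synthesis by itself was not shown.

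In E17.5 liver, interferon response genes were lower in MO than in CT erythroid-like cells. All 19 members of the list were lower, with a median log2 ratio of −1.06 (percentile 0), and so were the 8 members that passed the rule against carried-over RNA, with a median of −1.32. Isg15, a ubiquitin-like protein induced by interferon, stood at 280 CPM (UMIs scaled to the same non-globin total) in MO and 1307 in CT (−2.22, −2.26 to −2.19). Rsad2 stood at −1.54 (−1.58 to −1.50), Ifit1 at −2.32 (−2.68 to −1.99), Usp18, which removes Isg15 from proteins, at −1.36 (−1.60 to −1.13) and the transcription factor genes Irf7 at −1.29 (−1.47 to −1.12) and Stat1 at −0.94 (−1.07 to −0.81). DNA replication and mitosis genes were higher in MO, in 42 of 42 S phase members (median 0.27) and 49 of 51 G2 and M phase members (median 0.26).

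Among E17.5 erythroid-like cells, those leading genes also lead cluster 6, and with a common cluster composition the interferon median was −0.71, the S phase median 0.040, inside the range of random lists, and the G2 and M phase median 0.16. The same list was lower in 19 of 19 measured members in neutrophil or granulocyte progenitor-like cells (median −0.97), in 16 of 16 in B lymphoid-like cells (−0.87) and in 13 of 19 in macrophage-like cells (−0.09). The other named genes that were lower included Igtp at −1.33 (−1.67 to −1.01), Irgm2 at −1.23 (−1.60 to −0.88), Apol11b at −0.98 (−1.22 to −0.75) and the platelet gene Ppbp at −1.34 (−1.78 to −0.93). The highest were Slc15a2 at 1.27 (0.98 to 1.58), Tsix at 1.23 (0.88 to 1.60), Muc6 at 1.09 (0.73 to 1.47) and the water and glycerol channel gene Aqp3 at 0.88 (0.69 to 1.08), followed by Cracr2a, Ston2, Ampd2, Ctla4 and the histone genes Hist1h3i and Hist1h1b, the last at 0.54 (0.52 to 0.56). Ctla4, at 0.95, turned to −0.20 in the other file set of these samples. Megakaryocyte or platelet-like cells (47 CT and 40 MO) and T or NK lymphoid-like cells (23 and 22) were too few for the rule against carried-over RNA. Ppbp and Ctla4 were thus not checked against these classes, and RNA from them is not ruled out. Tsix is read from the strand opposite Xist, whose level was 430 CPM in MO and 267 in CT over the whole library, and Y-linked genes were at 39.2 and 77.0 CPM, so the pools differed in sex-linked transcripts.

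Mitochondrially encoded transcripts were lower in 12 of 13 members (median −0.43), from mt-Cytb at −0.72 (−0.73 to −0.70) to mt-Nd6 at 0.02 (−0.16 to 0.19). Mitophagy and enucleation genes were lower in 13 of 19, with a median of −0.15 that turned to 0.05 with a common cluster composition and 0.04 with globins in the scale. Heme synthesis genes had a median of 0.11, with 9 of 15 higher, Cpox at 0.25 (0.23 to 0.27) and Alas2 at −0.34 (−0.35 to −0.32). Erythroid iron handling lay at 0.05 (−0.0042 with a common cluster composition), with Tfrc, the transferrin receptor, at 0.43 (0.40 to 0.46) and Ftl1 at −0.41 (−0.43 to −0.40). Cholesterol synthesis (16 of 16 lower, median −0.31), fatty acid synthesis (11 of 11 lower, −0.54) and lipid uptake, storage and oxidation genes (17 of 20 lower, −0.54) were lower, but 1, 1 and 7 of their members passed the rule against carried-over RNA, and hepatocyte maturation genes were lower in the same cells by a median of −1.19. The lipid uptake median was −0.27 with a common cluster composition.

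Globins took 49.8% (49.7 to 49.8) of the UMIs of MO and 56.0% (55.9 to 56.0) of those of CT erythroid-like cells at E17.5. The embryonic share of beta-like globin UMIs was 0.0140% (0.0134 to 0.0146) in MO and 0.00639% (0.00602 to 0.00678) in CT, that of alpha-like globin UMIs 0.00374% and 0.00476%, and 1 of 8040 and 0 of 10019 cells (allowing up to 0.0368%) held mostly embryonic beta-like globin. In neutrophil or granulocyte progenitor-like cells, which should not make globin, the beta-like share was 0.00271% (0.000737 to 0.00693) in MO and 0.00887% (0.00556 to 0.0134) in CT and the alpha-like share 0.0722% and 0.0207%, so the CT beta-like and both alpha-like shares of erythroid-like cells were at or below this background. The MO beta-like share lay above it but below the 0.0436% (0.0160 to 0.0949) of MO hepatocyte-like cells, and so was not set apart from background. B lymphoid-like cells formed 4.89% (4.51 to 5.29) of MO and 6.66% (6.27 to 7.06) of CT cells, stromal or stellate-like cells 1.86% (1.63 to 2.12) and 0.734% (0.605 to 0.882), but 0.343% and 0.278% without a barcode filter and 0.949% and 0.701% at Leiden resolution 2.0, and neutrophil or granulocyte progenitor-like cells numbered 1233 and 1374. The globin difference of −6.19 points turned to 1.73 with a common cluster composition and was −3.43 in the other file set, while the difference of 1.77 points in the erythroid-like share ranged from −1.51, with the clusters led by ribosomal RNA repeat genes counted in, to 9.37 in the other file set.

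**Figure D3:**
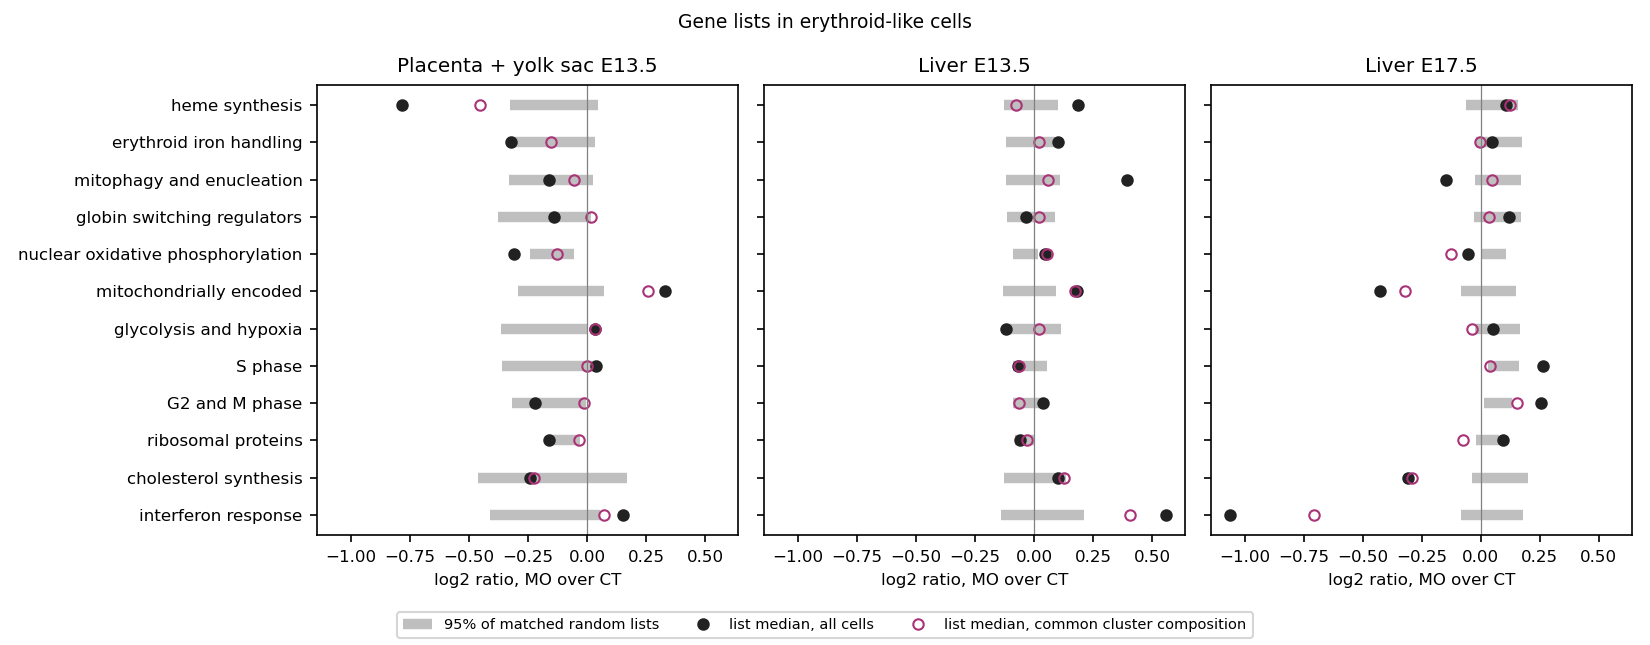
Filled points give the median log2 ratio of MO over CT for 12 gene lists in erythroid-like cells of the 3 tissues, open points the median with a common cluster composition, and grey bars the middle 95% of random lists matched on expression. Heme synthesis in placenta with yolk sac (−0.78) and interferon response in E17.5 liver (−1.06) lie farthest below their grey bars. The heme synthesis value shrinks to −0.45 with a common cluster composition, and further without cluster 12, which is not drawn.

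In placenta with yolk sac, erythroid-like cells fell into clusters dominated by embryonic and by adult globins, and these are described apart because cluster 12 has Reln, a stromal marker, among its leading genes. By its other markers that cluster was erythroid, with a score of 5.87 from 16 erythroid markers and late erythroid next at 3.67. Globins took 82.0% of its UMIs, and 86.25% of its beta-like globin was embryonic. Values without it are therefore not a cleaner estimate. Embryonic-globin clusters (10 and 12) held 1100 CT and 1523 MO cells, and adult-globin clusters (5, 6, 9 and 11) 1936 and 2455. In the embryonic-globin clusters, Hba-x, the embryonic alpha-like globin, took 8.18% (8.17 to 8.19) of globin UMIs in MO and 11.2% (11.1 to 11.2) in CT, and Hbb-bh1 0.541% (0.538 to 0.544) and 1.28% (1.27 to 1.28). Hbb-y was near equal at 49.6% and 50.3%. Over all erythroid-like clusters, 14 of 15 heme synthesis genes were lower in MO, with a median log2 ratio of −0.78 (percentile 0) against −0.17 for all genes. That median shrank to −0.45 with a common cluster composition, and further without cluster 12.

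The embryonic share of alpha-like globin UMIs in the embryonic-globin clusters was 19.6% in MO and 27.3% in CT, at 17.6% and 19.2% in cluster 10 and 28.3% and 36.0% in cluster 12. The embryonic share of beta-like globin UMIs was 86.0% and 87.2% there and 0.674% and 0.644% in the adult-globin clusters. Over all erythroid-like cells it was 43.8% (43.8 to 43.8) in MO and 45.5% (45.5 to 45.6) in CT, globins 88.9% and 87.3% of all UMIs, and cells with mostly embryonic beta-like globin 38.0% (36.4 to 39.5) and 36.1% (34.4 to 37.9), with 50 and 17 cells near the dividing share. In trophoblast giant cell-like cells, which should not make globin, globins took 15.7% of UMIs in MO and 4.10% in CT.

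Of the heme synthesis genes in these cells, Tmem14c, a mitochondrial porphyrin transporter, stood at −1.53 (−1.69 to −1.38), Alad at −1.27 (−1.38 to −1.16) and Alas2 at −0.10 (−0.12 to −0.08). The 10 lowest genes ran from Ccdc141 at −2.11 (−2.30 to −1.92) to Klf1, a master regulator of red cell genes, at −1.50 (−1.71 to −1.30), and included Slc25a21, the iron reductase gene Steap3, Exoc6 at −1.95 (−2.24 to −1.67), and Pigq at −1.51 (−1.73 to −1.30), with Pus10, Tuft1, Ninl and Slc30a10. All 10 had megakaryocyte or platelet-like cells, a class with a smaller share in MO, as the class with the highest level elsewhere. Klf1 stood at 0.286 of the level there. That class was cluster 19, with globins at 54.4% of UMIs, Hemgn among its leading genes and an erythroid marker score of 5.575 beside its own 5.502. At Leiden resolution 2.0 it held 42 CT and 42 MO cells with a median of 1910 UMIs, against 26889.5 here. A Hemgn-led cluster of 80 CT and 38 MO cells was then named erythroid-like. The class may thus hold erythroid cells, so its level does not show where these transcripts came from. The highest were P2rx7 at 1.23 (0.93 to 1.55), Qtrt1 at 1.10 (0.86 to 1.35), Nkain2, Dpp7, AW047730, Phf23 at 0.85 (0.72 to 0.99), Dlg4, Ftl1-ps1, Malat1 at 0.58 (0.57 to 0.58) and Impact. Erythroid iron handling genes were lower in 15 of 19 (median −0.32) and nuclear oxidative phosphorylation genes in 52 of 58 (−0.31), while 12 of 13 mitochondrially encoded transcripts were higher (0.33). With a common cluster composition, iron handling stood at −0.15 and oxidative phosphorylation at −0.13, both inside the range of random lists, heme synthesis at −0.45 and mitochondrially encoded transcripts at 0.26. Cluster 12, which Ccdc141 and Slc25a21 lead, weighs on these values. It holds 503 CT and 280 MO cells with mostly embryonic beta-like globin, so its removal lowers the CT embryonic shares more by construction. Without it, the heme synthesis median was −0.19, the mitochondrially encoded median −0.01, Ccdc141, Exoc6 and Tuft1 turned to 0.26, 0.17 and 0.06, and the MO minus CT differences in embryonic beta-like share, embryonic alpha-like share and globin share turned from −1.72, −4.33 and 1.65 to 7.55, 1.24 and −0.0595 points. The beta-like difference was also 0.391 with the stricter barcode filter.

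Trophoblast giant cell-like cells, which make placental hormones, had more transcripts of several prolactin-family genes in MO. Prl7a1 stood at 1.55 (1.32 to 1.79), Prl2c2 at 1.72 (1.29 to 2.18), Prl2c3 at 1.34 (1.15 to 1.53) and Prl2c5 at 1.02 (0.90 to 1.14), while Ctsq, a placental cathepsin gene, stood at −1.87 (−2.04 to −1.71). For all 4 prolactin-family genes the highest level elsewhere was in spongiotrophoblast or glycogen trophoblast-like cells, which took a larger share in MO. Relative to the level there, Prl2c5 stood at only 0.213, Prl2c2 at 0.724, Prl7a1 at 0.953 and Prl2c3 at 1.45. Carried-over RNA is thus not ruled out for these genes, above all for Prl2c5. S phase genes were higher in 32 of 40 members (median 0.36, percentile 100), Mki67 was at −1.24 (−1.70 to −0.80) and the endoplasmic reticulum chaperone gene Hspa5 at −0.88 (−1.03 to −0.73). Clusters 14 and 15 hold this class and are led by genes that include Ctsq and the Prl2c genes with Prl7a1. With a common composition of these clusters, Prl7a1 stood at 1.39, Prl2c2 at 1.56 and Ctsq at −1.81. At Leiden resolution 2.0 the class held 383 CT and 375 MO cells, against 584 and 581 here. The cells led by Prl2c3 and Prl7a1 were then a cluster of their own, with 55 CT and 78 MO cells. A shift in their share within cluster 15 may thus remain in these values. The Prl2c genes are close paralogs, so counts among them are uncertain. Other genes that were higher included Pdcd10, Hspb1, Nostrin, Sct, Hmgb1 and Pak1ip1 at 0.55 (0.33 to 0.77), and other lower genes Dst at −1.11 (−1.30 to −0.93), Map1b, Cbx7, Arid1a, Plec, Tgfbr3, Ep400, Srgap3 and Shroom4. Placental nutrient transport genes were lower in 9 of 12 (median −0.30). With a common cluster composition their median was −0.28, inside the range of random lists. Spongiotrophoblast or glycogen trophoblast-like cells formed 5.26% (4.78 to 5.77) of MO and 3.94% (3.50 to 4.42) of CT cells, endothelial-like cells 3.02% (2.66 to 3.42) and 4.76% (4.28 to 5.28), and megakaryocyte or platelet-like cells 0.609% (0.451 to 0.804) and 1.42% (1.15 to 1.72). At Leiden resolution 2.0 the first were 6.92% and 6.28% and the last 0.522% and 0.589%.

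Between E13.5 and E17.5, liver erythroid-like cells gained globin, heme synthesis and mitophagy transcripts and lost embryonic globin in both diets. Globins rose from 14.6% to 56.0% of UMIs in CT and from 27.4% to 49.8% in MO. The heme synthesis list stood at a median log2 ratio of E17.5 over E13.5 of 1.503 in CT and 1.447 in MO, with 13 of 15 members higher in each, and mitophagy and enucleation genes at 2.06 and 1.60, with 15 of 19 higher. Interferon response genes stood at 2.72 in CT (17 of 18 higher) and 0.66 in MO (11 of 16). The all-gene medians were −0.30 and −0.27. The genes named by the rule as higher were Rsad2 at 11.6 in CT and 8.19 in MO, Isg20 at 6.83 and 5.74, the fatty acid receptor gene Cd36 at 6.88 and 5.06, Ndufa4l2 at 4.82 and 5.79 and the oxygen sensor gene Egln3 at 5.09 and 4.87. Those lower were Fosb at −5.93 and −5.62, Igf2bp1, an RNA-binding protein of fetal cells, at −4.51 and −3.84, Relb at −3.77 and −3.67, Nfkbia at −3.26 and −3.33 and Slc35d2 at −3.32 and −3.83. Of the Rsad2 UMIs, 17263 of 17270 in CT and 6955 of 6968 in MO came from E17.5, so its E13.5 level was near the floor. Dissociation and immediate early genes were lower in 16 of 20 members in each diet (medians −1.42 and −1.55). Day and library preparation cannot be told apart here, and with globins in the scale the heme synthesis medians were 0.55 and 0.91. The deposited E13.5 barcodes also end at 3305 (CT) and 2125 (MO) UMIs, and those of E17.5 at 500. No common floor was applied between days, so part of these changes may reflect which barcodes were kept.

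The lists not yet named gave these medians in erythroid-like cells of placenta with yolk sac, E13.5 liver and E17.5 liver. Heme breakdown and export stood at 0.03, 0.24 and −0.03, glycolysis and hypoxia at 0.03, −0.12 and 0.05, p53 targets at 0.14, −0.17 and −0.10, the integrated stress and unfolded protein response at 0.12, −0.05 and −0.02, antioxidant genes at 0.04, 0.08 and −0.11, and inflammatory signalling at −0.11, 0.94 and −0.54. Ccl2 and Ccl3 of the inflammatory list lead the monocyte or dendritic-like cluster of E13.5 liver. That class, and the neutrophil-like and macrophage-like cells, took larger shares of the MO library there. Carried-over RNA is thus not ruled out for the inflammatory value of 0.94. Lists of genes made mainly by other cells stood at −0.06, 0.83 and −0.89 (systemic iron genes of the liver), 0.52, 1.23 and −0.53 (erythropoietic and growth signals) and −0.11, 0.40 and −0.31 (angiogenesis). Ribosomal protein genes stood at −0.16, −0.06 and 0.09, and dissociation and immediate early genes at −0.04, −0.03 and 0.00. Y-linked genes stood at 0.40, 0.52 and −0.80. Given a common cluster composition, heme breakdown and export stood at −0.11, 0.072 and 0.027, glycolysis and hypoxia at 0.033, 0.022 and −0.035, and p53 targets at 0.040, −0.090 and −0.14. The stress response list then stood at 0.036, −0.091 and 0.028, antioxidant genes at −0.0020, −0.0053 and −0.031, inflammatory signalling at −0.26, 0.61 and −0.28, and ribosomal protein genes at −0.036, −0.027 and −0.074. Erythropoietic and growth signals stood at 0.43, 1.16 and −0.17, systemic iron genes at −0.12, 0.74 and −0.55, and dissociation genes at −0.073, −0.077 and −0.027.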

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

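Of the tests below, those of free globin RNA, of cluster composition and of the Isg15 and Rsad2 levels were chosen only after the result was seen, and the alternatives quoted beside them were too. The values below stand here because the MO minus CT difference, or the log2 ratio of MO over CT, pointed one way in some tissue or day and the other way in another. With 1 library per group, none of these differences between tissues or days was tested.

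The share of erythroid-like cells differed by 6.89 percentage points in placenta with yolk sac, −8.11 in E13.5 liver and 1.77 in E17.5 liver. The globin share of their UMIs differed by 12.7 points in E13.5 liver and −6.19 in E17.5 liver. The embryonic share of beta-like globin differed by −1.72 points in placenta with yolk sac and 0.844 in E13.5 liver, and that of alpha-like globin by −4.33, 0.0502 and, in E17.5 liver, −0.00102, where both shares were at or below those of neutrophil-like cells. The heme synthesis median was −0.78 in placenta with yolk sac and 0.19 in E13.5 liver. The glycolysis and hypoxia median was 0.031 and −0.12 there. For interferon response genes, E13.5 and E17.5 liver gave 0.56 and −1.06, for lipid uptake, storage and oxidation 0.18 and −0.54, for mitochondrially encoded transcripts 0.18 and −0.43, and for mitophagy and enucleation 0.39 and −0.15. Most interferon members measured in E13.5 liver failed the rule against carried-over RNA, and those that passed had a smaller median, as given above. Nuclear oxidative phosphorylation stood at −0.31 in placenta with yolk sac, 0.047 in E13.5 liver and −0.052 in E17.5 liver.

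Several of these opposite directions were lost under another setting. With a common cluster composition, the globin share differed by 4.56 and 1.73 points in E13.5 and E17.5 liver, and mitophagy and enucleation stood at 0.061 and 0.047, both inside the range of random lists. In placenta with yolk sac and E13.5 liver, heme synthesis was then −0.45 and −0.078, and glycolysis and hypoxia 0.033 and 0.022. Oxidative phosphorylation kept its directions, at −0.13 in placenta with yolk sac, inside the range of random lists, 0.055 and −0.13 in E13.5 and E17.5 liver, and lipid genes theirs at 0.15, inside that range, and −0.27. With globins in the scale, E13.5 liver turned to −0.057 for lipid genes and −0.049 for mitochondrially encoded transcripts, the direction of E17.5 liver. Without cluster 12, the embryonic shares of placenta with yolk sac turned to 7.55 and 1.24 points, the direction of E13.5 liver. That cluster holds 503 CT and 280 MO cells with mostly embryonic beta-like globin. Its removal therefore lowers the CT shares more by construction and does not test the direction.

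The higher globin share of MO erythroid-like cells in E13.5 liver could come from the lower UMI edge of the deposited barcodes, from free globin RNA, from more mature cells in the pool, or from the diet, which was not tested apart from the library. Among the 3000 barcodes with most UMIs of each library the difference was 7.41 points, over 0.5 of the full 12.7, which argues against the edge as the whole cause, but it was 4.80 above a common UMI floor, so a part stays open. Free globin RNA should raise all classes alike, and hepatocyte-like cells rose by 2.82 points, which argues against it as the whole cause; this test replaced a first one, on late minus early erythroid markers, which had come out undecided at a log2 difference of 0.453 (0.292 to 0.699) against its bound of 0.3. With a common cluster composition 4.56 points remained, 35.8% of the full difference, between the bounds set for and against a shift in maturation. That shift stays open, and a shift in maturation in the embryos cannot be told apart from one made in sampling the pool.

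The lower interferon response of MO erythroid-like cells in E17.5 liver could come from free RNA, from a few embryos of the CT pool, or from the diet, which was not tested apart from the library. Free RNA was given its condition in advance, and that was met: B lymphoid-like and neutrophil or granulocyte progenitor-like cells lay within 0.191 of the erythroid-like median (the largest distance, put in place of the smallest after the result was seen), while the class with the highest level depended on the measure, since without B2m, H2-K1, H2-D1, Psmb8 and Ifitm3 erythroid-like cells led in CT (2468 CPM, macrophage-like 1800) and macrophage-like cells in MO (1473, erythroid-like 776). Isg15, however, was 21.5-fold (18.9 to 24.6) higher per non-globin UMI and 12.4-fold (10.8 to 14.2) higher per cell in CT erythroid-like than in B lymphoid-like cells, and Rsad2 16.0-fold (13.9 to 18.6) and 9.23-fold (7.99 to 10.7), which argues against free RNA for these genes and leaves the other members open, as Ifit1 at 7.34-fold (3.82 to 16.2). Cells from a few embryos could differ in sex, and the ratio of Y-linked to Xist UMIs in the interferon-led cluster was 4.08 (3.09 to 5.39) times that of the other erythroid-like clusters, past the bound of 3 set in advance. It was judged undecided after it was seen, because that ratio also ran from 0.171 to 0.744 among the other clusters, a spread of 4.35, and was 1.57 times that of the cluster nearest in globin share.

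The adult-globin erythroid-like clusters of placenta with yolk sac may be blood of the mother, definitive cells of the fetus, or both. Blood of the mother carries no Y-linked transcripts, and these clusters held 16.1 CPM of them against 42.4 in the embryonic-globin clusters (64 and 346 UMIs). The ratio of 0.3801 (0.286 to 0.498) lay between the bounds set for and against the mother's cells, and Y-linked levels can also differ with maturation and free RNA. By cluster, Y-linked levels were 19.5 (CT) and 18.9 CPM (MO) in cluster 9. They were 5.74 and 10.1 in cluster 5 and 4.69 and 14.7 in cluster 6, from 2 to 7 UMIs per library. The clusters were not tested apart, and they may differ in origin. The origin of these clusters cannot be told apart with these values, and no difference between diets in them was assigned to the fetus.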

How the results depend on the processing

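Here the UMI floor, the 5000 deepest barcodes, the doublet scores, the clusters led by ribosomal RNA repeat genes, cluster 12, the interferon-led cluster and the common composition were chosen after the data were seen, as were the lists followed. Differences are MO minus CT in percentage points, list values are medians of log2 ratios, and those between days are E17.5 minus or over E13.5. Of the main values under each alternative, 74 stayed within their 95% counting interval, 76 left it and 11 changed sign, counted as such only where the interval excluded 0 or the list was outside the middle 95% of random lists, or for any list between days. For other values, which include list medians, the numbers were 398, 148 and 24. The 398 and 148 include list medians that changed sign from inside the range of random lists, such as S phase in placenta with yolk sac, at −0.61 without a barcode filter. All 20 named genes of each comparison of erythroid-like cells kept their direction except 3 without cluster 12 and 1 in the other E17.5 matrices, and all 10 between days did. The named genes of trophoblast giant cell-like and hepatocyte-like cells were not rerun under these alternatives, other than the common cluster composition. The barcode filter removes none of the E13.5 liver barcodes, so that alternative gives no value there. No paired analysis was possible because each group has 1 library. Depth limits E13.5 liver, where the MO library holds fewer UMIs and a lower edge, and placenta with yolk sac, where 3475 genes could be considered in erythroid-like cells. The cause was not tested for any change below unless the alternative itself shows it.

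Without a barcode filter, placenta with yolk sac gave embryonic shares of −3.09 (beta-like) and −5.30 (alpha-like), a globin share of 2.65, heme synthesis of −0.67 and glycolysis and hypoxia, turned, of −0.084. E17.5 liver gave an erythroid-like share of 6.72, embryonic shares of 0.00511 and −0.00333 and a globin share of −4.70, with 18.4% of CT and 10.4% of MO cells then unnamed. Between days, CT heme synthesis was 1.53 and globin shares 39.1 (CT) and 21.7 (MO). With at least 1000 UMIs and 300 genes, the beta-like embryonic share of placenta with yolk sac turned to 0.391, its globin share was 1.42 and the share of mostly embryonic cells 4.15. The globin share was 12.8 in E13.5 liver, and E17.5 liver gave an erythroid-like share of 0.0297, a beta-like embryonic share of 0.0100 and a globin share of −5.23. Between days, heme synthesis was 1.65 (CT) and 1.58 (MO) and globin shares 37.8 and 19.8.

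At Leiden resolution 2.0, placenta with yolk sac gave embryonic shares of −3.02 and −5.36, a globin share of 2.68, heme synthesis of −0.67 and glycolysis and hypoxia turned to −0.12. The erythroid-like class there includes a cluster of 202 CT and 323 MO cells led by granzyme genes. E13.5 liver gave an erythroid-like share of −6.80, a globin share of 12.05 and heme synthesis of 0.16, and E17.5 liver an erythroid-like share of 3.68 and a globin share of −6.14. Without doublet removal, E17.5 liver gave embryonic shares of 0.00977 and −0.000380 and a globin share of −6.08. Without the 6% highest doublet scores, embryonic beta-like, embryonic alpha-like and globin shares were −1.50, −4.21 and 1.61 in placenta with yolk sac, 0.959, 0.114 and 12.8 in E13.5 liver, and 0.00455, −0.00355 and −6.55 in E17.5 liver. With the other E17.5 matrices (leave-one-out), the erythroid-like share differed by 9.37 and the globin share by −3.43, and 21.6% of CT and 10.6% of MO cells were then unnamed.

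Above the common UMI floor of E13.5 liver, the erythroid-like share differed by −22.7, embryonic shares by 0.649 and −0.0264, the last turned, and the globin share by 4.80, while heme synthesis turned to −0.13, iron handling to −0.041 and glycolysis and hypoxia to 0.017. With the 5000 deepest barcodes, the erythroid-like share differed by −11.4, the beta-like embryonic share by 1.02 and the globin share by 9.87, and heme synthesis was 0.13. A limit of 0.3 for mostly embryonic cells in E13.5 liver gave 1.52 and one of 0.7 turned the difference to −0.0499.

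With the clusters led by ribosomal RNA repeat genes counted as erythroid-like, placenta with yolk sac gave an erythroid-like share of 4.59, embryonic shares of −1.63 and −4.11, a globin share of 1.75 and glycolysis and hypoxia turned to −0.039. In E17.5 liver the erythroid-like share turned to −1.51, with embryonic shares of 0.00441 and −0.00498 and a globin share of −6.50. Without the interferon-led cluster, E17.5 liver gave an erythroid-like share of 2.96, a beta-like embryonic share of 0.00681 and a globin share of −5.86. Without cluster 12, placenta with yolk sac gave an erythroid-like share of 9.42, a share of mostly embryonic cells of 9.85 and heme synthesis of −0.19, and the embryonic shares turned to 7.55 and 1.24, the globin share to −0.0595, glycolysis and hypoxia to −0.018, mitochondrially encoded transcripts to −0.014 and interferon response to −0.13. Cluster 12 holds a larger part of the CT class, and the alternative takes out its embryonic globin.

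With a common cluster composition, placenta with yolk sac gave heme synthesis of −0.45 and a globin share of 0.922, and antioxidant genes turned to −0.00197. In E13.5 liver, heme synthesis turned to −0.078 and glycolysis and hypoxia to 0.022, and the globin share was 4.56. In E17.5 liver, mitophagy and enucleation turned to 0.047, ribosomal proteins to −0.074 and the globin share to 1.73.

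With globins in the scale, the median of all genes moved from −0.17 to −0.37 in placenta with yolk sac, from 0.02 to −0.22 in E13.5 liver, from 0.04 to 0.23 in E17.5 liver, and between days from −0.30 to −1.26 (CT) and from −0.27 to −0.80 (MO), and lists moved with it. Placenta with yolk sac gave heme synthesis of −0.98, and glycolysis and hypoxia turned to −0.17, interferon response to −0.047 and antioxidant genes to −0.16. In E13.5 liver, heme synthesis turned to −0.047, iron handling to −0.13, oxidative phosphorylation to −0.19, mitochondrially encoded transcripts to −0.049 and lipid genes to −0.057. In E17.5 liver, heme synthesis was 0.30, and mitophagy and enucleation turned to 0.043, oxidative phosphorylation to 0.14 and antioxidant genes to 0.080. Between days, heme synthesis was 0.55 (CT) and 0.91 (MO), and CT iron handling turned to −0.33. With TMM factors the all-gene medians were −0.02, −0.04 and 0.01, and −0.09 and 0.05 between days. Heme synthesis was then −0.63 in placenta with yolk sac, 0.12 in E13.5 liver and 1.71 (CT) and 1.77 (MO) between days, and oxidative phosphorylation in E13.5 liver turned to −0.014.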

Other observations

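Nothing in this part rests on a test. In trophoblast giant cell-like cells, 7 of 8 measured fatty acid synthesis genes (median log2 ratio −0.79, percentile 0.05) and 13 of 15 cholesterol synthesis genes (median −0.34) were lower in MO than in CT. Only 3 of those 8 pass the rule against carried-over RNA, with a median of −0.097, so the fatty acid value rests on genes far higher in another class. Of the 15, 7 pass it, with a median of −0.33. In hepatocyte-like cells of E13.5 liver both lists were lower as well, at −0.32 and −0.33, beside lower hepatocyte maturation genes. Mitochondrially encoded transcripts of giant cell-like cells were higher in 12 of 13 members (median 0.25).

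In neutrophil or granulocyte progenitor-like cells of E13.5 liver, 4.47% of beta-like globin UMIs were embryonic in MO and 0.389% in CT, against 2.55% and 1.83% in hepatocyte-like cells. In trophoblast giant cell-like cells of placenta with yolk sac, that share was 4.53% in MO and 19.7% in CT, while their globin share was 15.7% and 4.10%. Globin found outside erythroid-like cells thus differed in make-up as well as amount between libraries.

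Xist stood at 181 CPM in MO and 267 in CT placenta with yolk sac, 269 and 283 in E13.5 liver and 430 and 267 in E17.5 liver, and Y-linked genes at 43.3 and 30.8, 108 and 74.5, and 39.2 and 77.0. Blood and tissue of the mother would add Xist in placenta with yolk sac, and the sexes of the pooled embryos are not analysed here.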
